A study of Homo sapiens with 7 samples.

How the data were processed

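The data were RNA levels measured on single-colour Illumina bead arrays in human embryonic stem cells, 7 times with 2 replicate cultures each. Total RNA was purified on silica columns with DNA digestion, amplified linearly and labelled with Cy3, per the labels' protocols. The arrays were read out with BeadStudio 1.5, per the submitters' processing notes. The cell line and the array's chip position are not given in the sources used here. Groups are the hours in Activin A given by the sample titles, and the replicate number is that in the file headers. The series' design text describes the replicates as separate biological cultures.

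The deposited array files hold, per the file headers, an average bead intensity per probe on a linear scale and a detection score, a fraction from 0 to 1. From their values, the intensities were neither background-subtracted nor brought to a common scale: the lowest intensity per array was between 140.5 and 232, and the highest between 67735 and 73354. The detection score is read here as the rank of a probe among the array's negative controls, with 1 above all of them. A series table of deposited intensity values, 1 per time, was set against the array files. Over probes with a table value above 2000, a straight line of the mean of the 2 arrays on the column had a slope of 0.997 at 0 h and 1.24 to 1.41 at the other times, and values below 26 were blank, which fits a mean of both arrays with a constant background taken off and scaling to the 0 h level. How the authors made that table is not given in the sources used here. Its medians were 244 at 0 h, 253 at 12 h, 256 at 24 h, 259 at 36 h, 262 at 48 h and 72 h and 285 at 96 h. Its log2 changes from 0 h correlated with those used here at r between 0.989 and 0.994 across 10912 to 11003 probes, which are not independent. It served only as an alternative for the 4 named probes.

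Of the 24354 features per array, 4 are control features with bacterial gene names, left out of all tests, and 24350 are human probes identified by a sequence number. The files do not pair these identifiers with gene names. None of the identifiers matched the names, synonyms or accessions of the gene table used (0 of 24350), so results are per probe. The 22 gene lists fixed before the data were examined, the choice of 1 probe per gene and the rule for naming genes needed symbols and could not be applied. The 4 named probes are the first 2 rises and the first 2 falls at 96 h by the fixed ranking: an adjusted p below 0.05, both arrays of 1 time on the same side of both arrays of the other, then fitted log2 change, which also ranks probes below detection at 1 of the times. Other sizes called largest in the text are ranked with such levels at their bound, an order set after the values were seen. Naming the 4 probes by identifier was decided after the values were seen, because the rule had asked for symbols.

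Background was corrected by normal-exponential convolution with negative control parameters inferred from the detection scores, with an offset of 16, followed by quantile normalization and log2 (nec and normalizeBetweenArrays in limma 3.58.1, R 4.3.3). Quantile normalization gives every array the same distribution, so it removes any change shared by most probes and a balance of rises and falls is relative to it. A probe counted as detected on an array at a score above 0.99. The 11444 probes detected on both arrays of at least 1 time were tested, and 12906 were not. Of the human probes, 9004 were detected on all 14 arrays and 11339 on none.

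A linear model with 1 mean per time was fitted to all 14 arrays (7 residual degrees of freedom) with lmFit and eBayes in limma, without covariates. The 12 contrasts were each later time against 0 h, each time against the one before it, and 96 h against 24 h, all two-sided. A moderated F test covered the 6 contrasts against 0 h. Adjusted p-values are Benjamini-Hochberg values over the 11444 probes, with a threshold of 0.05, and every adjusted p and every rise or fall in the text comes from this limma fit. Folds are of background-corrected intensities plus the offset, which understates changes of dim probes. For bounded folds, the level on each array that did not detect the probe was set to the higher of its own value and the lowest value among the array's detected probes, and the fold is given as at least that size. Applying this also where 1 of the 2 arrays detected the probe was decided after the values were seen. No fold is given where both times were below detection.

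The procedure was tested on simulated data: 200 probes of the 11444 were changed by known folds between 0 h and 96 h. It recovered 6% of 50 probes changed 1.25-fold, 40% at 1.5-fold, 82% at 2-fold and 100% at 4-fold, with 8 false calls. Unchanged groups gave no false call at 24 h (0 of 11444). In this simulation small changes were often missed with 2 arrays per time. The recovered shares need not hold in the data, where 52.2% of the tested probes were called at 96 h. A larger share of changed probes makes the adjusted threshold less strict. The simulated noise was independent between probes, and background correction and normalization were not simulated.

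Alternatives fixed before the data were examined were median scaling, cyclic loess, no background correction, an offset of 50, no detection filter, detection on all 14 arrays, a variance trend with and without robust estimation, array weights, a fit of only the 4 arrays compared, a 2-fold minimum, leaving out each array in turn, and the series table. A block for the replicate number, an F test without the 0 h arrays and detection scores over 0.95 or of 1 were chosen after seeing the data. When 1 array of a time was left out, the remaining array was taken to vary like the others. Probes gained or lost from detection were then judged on the remaining array alone, which can only raise their numbers. Figures were drawn with matplotlib.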

Results

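Transcript levels were followed in human embryonic stem cells over 96 h of exposure to Activin A, a ligand of the TGF-beta family that is widely used to direct pluripotent cells towards mesendoderm and endoderm. The cells had been adapted to a defined N2B27 medium, replated, and collected before the switch of growth factors (0 h), every 12 h up to 48 h, and then at 72 h and 96 h. At 0 h they had grown with FGF2 at 20 ng/ml and without Activin A, and at every later time with Activin A at 100 ng/ml and without FGF2, a growth factor used to maintain human embryonic stem cells. Each of the 7 times had 2 replicate cultures, each on its own single-colour Illumina array, which gave 14 arrays. Activin A addition, FGF2 removal and time in culture changed together, so none of the comparisons against 0 h separates them. The median bead intensity per array was 251 and 256 at 0 h and between 293 and 365 on the other 12 arrays, and between 10275 and 11100 of the 24350 human probes were detected per array. With 2 arrays per time, the number of arrays limits the precision of each value. The files identify probes by sequence number without gene names, so results are given for probes, and the 4 probes named below rank first and second among rises and among falls at 96 h by fitted log2 change. Where an array did not detect a probe, the fold is a lower bound against the detection limit for background-corrected values, and the sizes and counts called bounded use that limit.

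The transcriptome moved away from the 0 h state with time. Of the 11444 probes tested, 6846 (59.8%) changed over the time course in limma's moderated F test over the 6 comparisons against 0 h. The first principal component held 60.5% of the variance and ordered the times, from -33.1 and -33.7 on the 0 h arrays to 52.1 and 50.9 on the 96 h arrays. The second component held 12.4%, was lowest at 0 h (-22.8 and -23.9), highest at 48 h (17.5 and 18.7) and low again at 96 h (-15.2 and -13.6). Replicate arrays stayed close to each other, with Pearson correlations across probes between 0.989 and 0.995, though probes are not independent replicates. The root-mean-square log2 change from 0 h, after subtraction of the variance expected from replicate error, grew from 0.30 at 12 h to 0.33 at 24 h, 0.43 at 36 h, 0.53 at 48 h, 0.68 at 72 h and 0.81 at 96 h. Among the 6846 probes, 1793 lay farthest above 0 h at 96 h and 2056 farthest below at 96 h, while 354 were farthest above and 269 farthest below at 12 h.

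**Figure D1:**
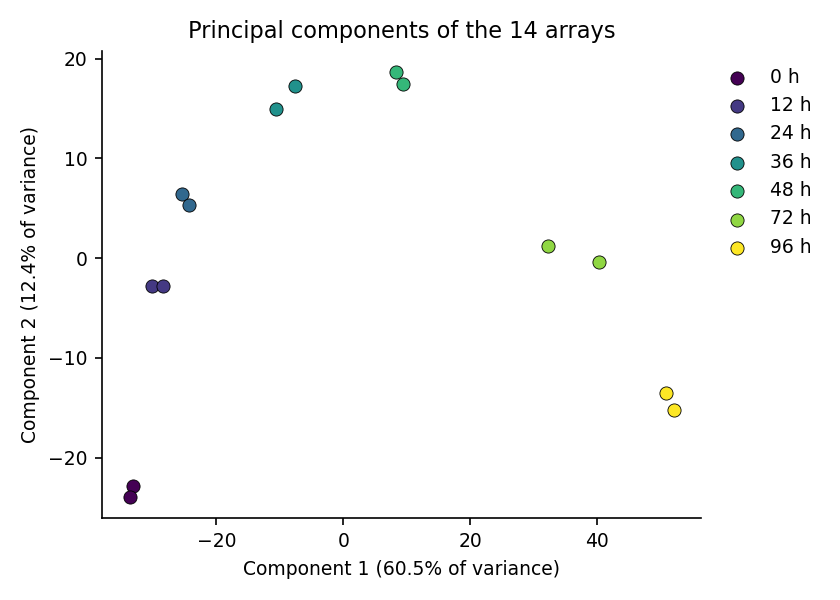
First and second principal components of the normalized log2 intensities of the 11444 tested probes, with 1 point per array and colour for hours in Activin A. The 0 h arrays lie at -33.1 and -33.7 on the first component and the 96 h arrays at 52.1 and 50.9, with the other times between them.

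The earliest comparison asked what had changed after 12 h. At that time 871 probes had risen and 705 had fallen, 1576 in all or 13.8% of those tested, with a median absolute log2 change of 0.53. Bounded changes of at least 2-fold were seen for 60 rises and 25 falls, 44 and 16 of them at probes detected on all arrays of both times, against 114 and 51 by fitted values. The largest bounded rise was at least 8.03-fold, at GI_22538469-S (adjusted p = 8.4e-06), which 1 of the 2 arrays at 0 h detected. The largest bounded fall was 3.82-fold, from 9.67 to 7.74 on the log2 scale, at a probe detected on all 4 arrays (adjusted p = 0.000175). The 0 h arrays were also the dimmest of the 14, as given above. The count fell to 577 without 12 h replicate 2, 663 without 12 h replicate 1, 597 without 0 h replicate 2 and 876 without 0 h replicate 1, to 532 with no detection filter and to 60 when only the 4 arrays compared were fitted. Scaling the arrays to a common median gave 1887 rises and 212 falls, 89.9% rises against 55.3% with quantile normalization. It put the median of all tested probes 0.15 above 0 on the log2 scale, so the balance of directions is relative to the scaling. Median scaling used the median over all features of an array. Most of these were below detection, so here and at the later times it rests on a level below detection.

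By 24 h, 832 probes were up and 720 down (1552 in all). Bounded changes of at least 2-fold were found for 87 rises and 54 falls (147 and 87 by fitted values). The largest bounded rise was at least 46.8-fold at GI_22538469-S, from 6.39 ± 0.18 at 0 h to 12.05 ± 0.22 at 24 h (mean log2 intensity ± SD, n = 2; adjusted p = 2.68e-08), with 1 of the 2 arrays at 0 h detecting it. The next bounded rise started below detection at 0 h and was at least 9.45-fold. The largest bounded falls were 4.12-fold and 3.95-fold, both at probes detected on all 4 arrays. Without 24 h replicate 1 the count was 547, without 24 h replicate 2 it was 919, without 0 h replicate 2 it was 736 and without 0 h replicate 1 it was 796, while no detection filter gave 582 and a fit of only the 4 arrays gave 218. Median scaling gave 84.9% rises against 53.6%, with the median probe at 0.13.

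After 36 h, 1196 probes stood above and 1133 below their 0 h level (2329 in all, 20.4%), of which 149 and 114 had a bounded change of at least 2-fold (221 and 159 by fitted values). Bounded rises of at least 4-fold numbered 42 and falls 3, or 57 and 8 by fitted values. Among probes detected on all arrays of both times these were 17 and 2. The largest bounded rise was again GI_22538469-S, at least 93.9-fold with an adjusted p of 4.01e-09, and the next 4 were at least 20.0-fold to 36.0-fold, all from below detection at 0 h. The largest bounded fall was 5.33-fold, at a probe detected on all 4 arrays (adjusted p = 5.07e-06). The count was 960 without 36 h replicate 1, 1271 without 36 h replicate 2, 1247 without 0 h replicate 2, 1229 with no detection filter and 1319 with only the 4 arrays fitted. Median scaling gave 80.9% rises against 51.4%, with the median probe at 0.14.

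At 48 h the changed probes numbered 3376, or 29.5% of those tested, with 1594 rises and 1782 falls. Bounded changes of at least 2-fold comprised 243 rises and 223 falls (363 and 309 by fitted values). GI_22538469-S stood at least 125-fold above 0 h (adjusted p = 1.53e-09) and GI_40288196-S at least 55.9-fold (adjusted p = 3.11e-08). The largest bounded fall was 6.70-fold, at a probe detected on both arrays of each time (adjusted p = 1.21e-06). No detection filter gave 2222 changed probes and a fit of only the 4 arrays 1441. The direction of the balance turned with scaling, from 47.2% rises to 65.3% with median scaling and 51.3% with cyclic loess.

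Still more probes differed at 72 h, 2224 up and 2530 down (4754 in all, 41.5%), with 461 rises and 387 falls of at least 2-fold when bounded (633 and 488 by fitted values). Bounded rises of at least 4-fold outnumbered falls, 128 to 27. GI_10835229-S had the largest bounded fall, 15.1-fold (adjusted p = 2.16e-07), followed by GI_38455405-S at 13.0-fold (adjusted p = 2.32e-07). Rises made up 46.8% of the called probes, 71.8% with median scaling, where the median probe lay at 0.15, and 52.8% with cyclic loess.

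The longest exposure gave the broadest difference from the starting cells. At 96 h, 2752 probes were higher and 3224 lower than at 0 h, 5976 in all or 52.2% of those tested, with a median absolute log2 change of 0.66. Bounded changes of at least 2-fold were found for 669 rises and 591 falls (915 and 689 by fitted values), and of at least 4-fold for 197 rises and 71 falls (273 and 94 by fitted values). Among probes detected on both arrays of both times, they were 102 rises and 54 falls, a share of 65.4% rises (exact Clopper-Pearson 95% interval 57.4 to 72.8, which treats probes as independent), whereas 2-fold changes in that set were even, 474 to 477. The share of rises among all called probes turned with scaling, from 46.1% to 76.0% with median scaling, where the median probe lay at 0.24, and 53.9% with cyclic loess. By fitted values 4-fold rises outnumbered falls under both, 340 to 44 with median scaling and 289 to 84 with cyclic loess, and so did those detected at both times, 156 to 18 and 117 to 43. No background correction left 86 rises and 8 falls of at least 4-fold, and an offset of 50 left 186 and 40. The rises and falls of at least 2-fold without background correction were 16 and 2 at 12 h, 34 and 8 at 24 h, 69 and 23 at 36 h, 113 and 35 at 48 h, 204 and 93 at 72 h and 326 and 162 at 96 h.

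**Figure D2:**
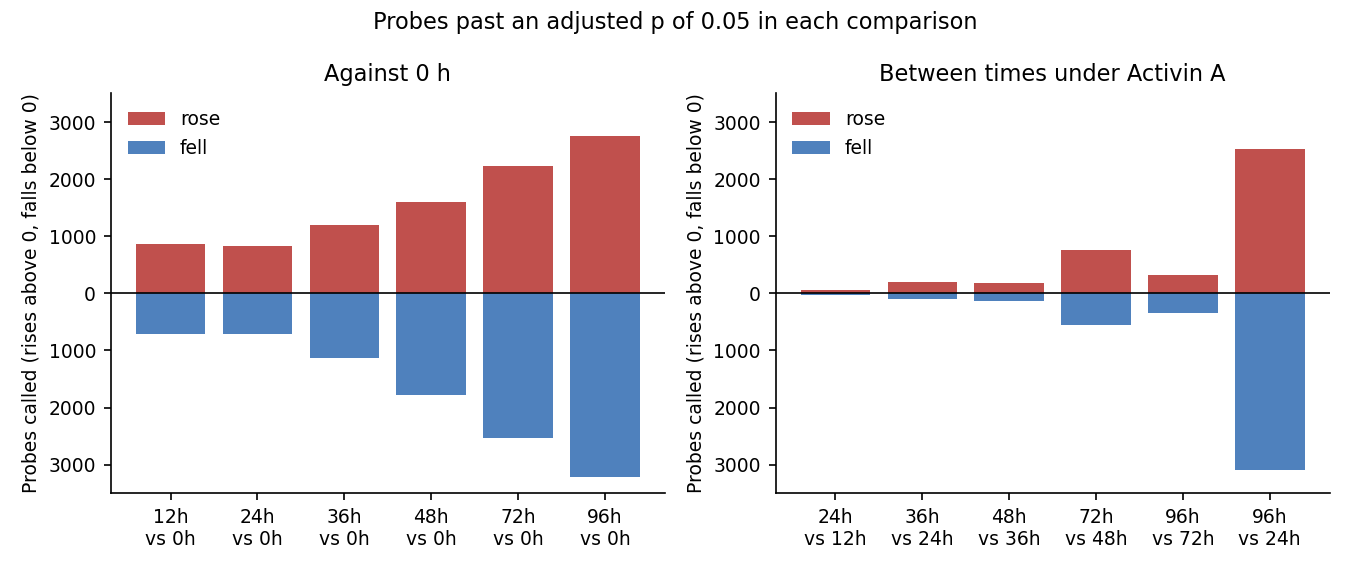
Number of probes called at an adjusted p of 0.05 in each comparison, with rises drawn above 0 and falls below 0. Against 0 h the called probes grew from 1576 at 12 h to 5976 at 96 h, and the split between rises and falls shown is that of quantile normalization, which median scaling moved to 89.9% rises at 12 h and 76.0% at 96 h.

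Of the 2 named rises, only GI_22538469-S was detected at 12 h. The 2 named falls were nearly alike up to 36 h, with log2 changes of -1.87 and -1.74 from 0 h. Differences in timing were not tested. GI_40288196-S had the largest fitted change at 96 h, but only a bound, which was the third largest after at least 148-fold for GI_22538469-S and 90.3-fold for a probe detected at both times. It was below detection on both arrays at 0 h (5.36 ± 0.31, SD, n = 2) and at 12 h (6.08 ± 0.28). No fold is given there, and the start of its rise is not known. It was called higher at 12 h than at 0 h, by 0.72 on the log2 scale (adjusted p = 0.0392). It reached 8.63 ± 0.08 at 24 h, 11.14 ± 0.37 at 36 h and 12.89 ± 0.04 at 96 h, at least 4.38-fold, 25.1-fold and 84.3-fold above 0 h (adjusted p = 1.49e-05, 1.5e-07 and 8.09e-09). GI_22538469-S had risen at least 8.03-fold by 12 h (9.50 ± 0.03, adjusted p = 8.4e-06). It levelled off at 13.75 ± 0.15 at 72 h and 13.71 ± 0.03 at 96 h, at least 148-fold above 0 h. Its change from 72 h to 96 h was -0.05 on the log2 scale with an adjusted p of 0.896. GI_10835229-S fell by 1.15 on the log2 scale by 24 h (adjusted p = 0.00287). Between 0 h and 96 h it fell by 4.19, from 12.60 ± 0.20 to 8.42 ± 0.12, which is 18.2-fold (adjusted p = 9.31e-08). Its largest step between neighbouring times was from 48 h to 72 h, 3.01-fold (adjusted p = 0.000678, or 0.0563 when only those 4 arrays were fitted). GI_38455405-S fell by 1.15 by 24 h (adjusted p = 0.00238) and was lowest at 72 h (6.75 ± 0.38), with 6.86 ± 0.12 at 96 h against 10.45 ± 0.06 at 0 h, 12.0-fold lower (adjusted p = 1.65e-07). The sizes rest on the background correction: without it, which shrinks changes of dim probes, GI_40288196-S rose 2.28-fold by 24 h and 27.1-fold by 96 h, below the bounds above, and GI_22538469-S, also below its bounds, 12.9-fold and 39.1-fold. The falls at 96 h were then 10.7-fold and 4.36-fold. With an offset of 50 the 4 fitted changes at 96 h were 101-fold, 113-fold, 16.6-fold and 9.53-fold.

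**Figure D3:**
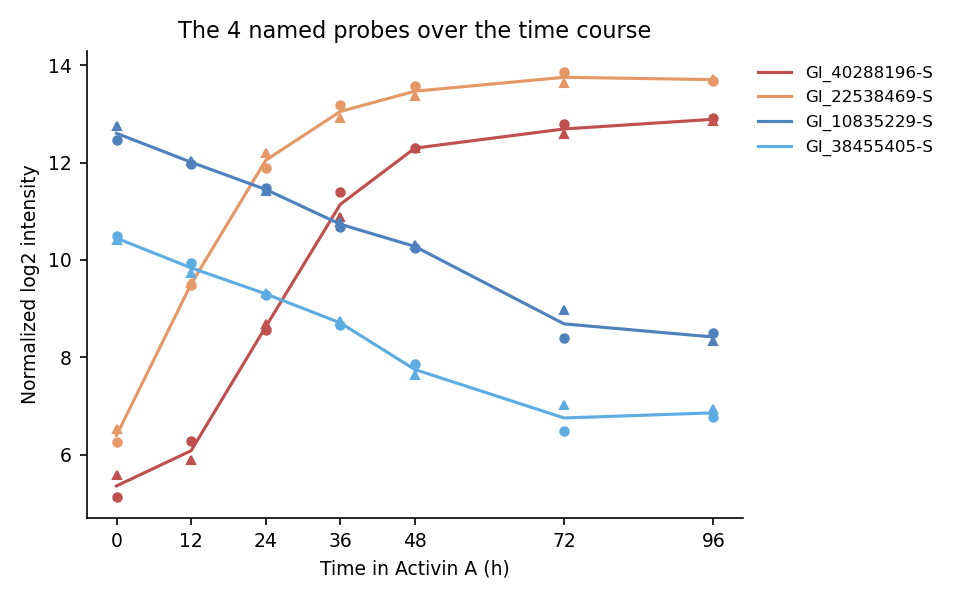
Normalized log2 intensity of the 4 named probes against hours in Activin A, with circles for replicate 1, triangles for replicate 2 and lines through the mean of the 2. GI_40288196-S and GI_22538469-S end at 12.89 and 13.71, and GI_10835229-S and GI_38455405-S at 8.42 and 6.86.

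Over the 12 h intervals from 12 h to 48 h, with both ends under Activin A, fewer probes changed than over the first 12 h. From 12 h to 24 h, 63 probes rose and 23 fell (86 in all), from 24 h to 36 h 201 rose and 94 fell (295), and from 36 h to 48 h 175 rose and 129 fell (304), against 1576 from 0 h to 12 h. The root-mean-square log2 changes, with replicate error subtracted, were 0.17, 0.22 and 0.23, against 0.30 in the first 12 h. Bounded changes of at least 2-fold followed this order, 85 in the first 12 h against 20, 57 and 54, but bounded rises of at least 4-fold did not, with 6 in the first 12 h and 12 from 24 h to 36 h. The largest bounded rises were 5.83-fold from 12 h to 24 h, at GI_22538469-S (adjusted p = 3.79e-05), 8.45-fold from 24 h to 36 h and 5.50-fold from 36 h to 48 h. The largest bounded falls were 2.01-fold, 2.28-fold and 2.17-fold, at probes detected on all arrays compared. None of the 3 intervals kept a call when only its 4 arrays were fitted in limma, where 1355, 1819 and 2009 probes had an unadjusted p below 0.05, while a variance trend gave 294, 530 and 745 calls and no background correction gave 305, 556 and 816. The count for 12 h to 24 h was 20 and 39 without 12 h replicates 2 and 1, 29 and 37 without 24 h replicates 2 and 1, 46 and 48 without 96 h replicates 2 and 1, and 56 without 36 h replicate 2. For 24 h to 36 h it was 66 and 130 without 36 h replicates 1 and 2, 107 and 110 without 24 h replicates 2 and 1, and 178 and 179 without 96 h replicates 2 and 1. For 36 h to 48 h it was 59 and 96 without 36 h replicates 2 and 1, 121 without 48 h replicate 2, and 173 and 185 without 96 h replicates 2 and 1. With no detection filter the 3 intervals had 29, 111 and 74 calls.

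The later intervals span 24 h each. From 48 h to 72 h, 765 probes rose and 547 fell (1312 in all), with 130 rises and 15 falls of at least 2-fold when bounded (182 and 25 by fitted values) and a largest bounded rise of 7.63-fold (adjusted p = 0.000392). The root-mean-square log2 change over this interval was 0.31. From 72 h to 96 h, 316 rose and 351 fell (667 in all), with 61 rises and 16 falls of at least 2-fold when bounded (77 and 21 by fitted values). The largest bounded fall of the last interval was at least 9.75-fold, from 9.52 on the log2 scale, at a probe detected on 1 of the 2 arrays at 96 h (adjusted p = 0.000573). The first of these counts was 333 without 72 h replicate 1, 513 without 48 h replicate 2, 527 with no detection filter and 87 with only the 4 arrays fitted. The second was 125 and 214 without 96 h replicates 1 and 2, 133 and 335 without 72 h replicates 2 and 1, 185 with no detection filter, 196 with only the 4 arrays fitted, 1133 with a variance trend, 1124 with trend and robust estimation and 1174 with no background correction. Median scaling gave 81.5% rises against 58.3% for 48 h to 72 h and 77.5% against 47.4% for 72 h to 96 h, and cyclic loess gave 56.5% for the latter.

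Late cells were set against early cells in the same medium, a comparison that does not use the 0 h arrays. The 2 times still differ in hours with Activin A, hours without FGF2 and hours in culture, which it does not separate. Between 24 h and 96 h, 2526 probes rose and 3092 fell (5618 in all, 49.1%), with 641 rises and 440 falls of at least 2-fold when bounded (799 and 529 by fitted values). The largest bounded rise was at least 94.7-fold (adjusted p = 1.23e-07), and the largest bounded fall, 8.18-fold, was at GI_10835229-S (adjusted p = 8.09e-07). Rises made up 45.0% of the calls, 62.9% with median scaling and 54.2% with cyclic loess.

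Part of the early changes turned back, and the larger part was still called at 96 h. Of the 832 probes up at 24 h, 460 (55.3%) were called up against 0 h at 96 h, and of the 720 down, 454 (63.1%) were called down. Of all 11444 tested probes, 2752 were called up and 3224 down at 96 h. Both comparisons use the same 0 h arrays, so a deviation of these arrays adds to such agreement. Of the same 832, 352 (42.3%) fell between 24 h and 96 h, 181 rose further and 299 had no later call. At 96 h, 48 of the 352 were still called above 0 h, 73 below and 231 neither. The 352 had a median log2 change from 0 h of 0.51 at 12 h, 0.57 at 24 h, 0.35 at 48 h and 0.03 at 96 h, whereas the 181 went from 0.66 at 24 h to 1.72 at 96 h. Of the 720 probes down at 24 h, 238 (33.1%) rose again, 224 fell further and 258 had no later call. The medians of the 238 were -0.36 at 12 h, -0.54 at 24 h and 0.17 at 96 h, and those of the 224 were -0.53 at 24 h and -1.34 at 96 h. Both steps were at least 2-fold for 15 of the 352 and 10 of the 238 when bounded, and for 22 and 15 by fitted values. Independent lists of these sizes would share 225 and 159 probes, but both comparisons use the 24 h arrays, which adds to such an overlap. They also share the estimate of each probe's spread, so probes with a low spread pass both tests more often. Parting the 24 h arrays does not remove this second effect. With each step tested on a different 24 h array, 140 and 107 probes rose then fell against 108 and 66.6 for independent lists, and 113 and 75 fell then rose against 74.7 and 46.1. The 352 became 126 and 220 without 24 h replicates 1 and 2, 168 and 201 without 0 h replicates 2 and 1, 230 and 232 without 96 h replicates 1 and 2, 124 with no detection filter and 60 when only the 4 arrays of each comparison were fitted. The 238 became 92 and 145 without 24 h replicates 1 and 2, 105 and 115 without 0 h replicates 1 and 2, 112 with median scaling, 73 with no detection filter and 20 with only the 4 arrays.

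**Figure D4:**
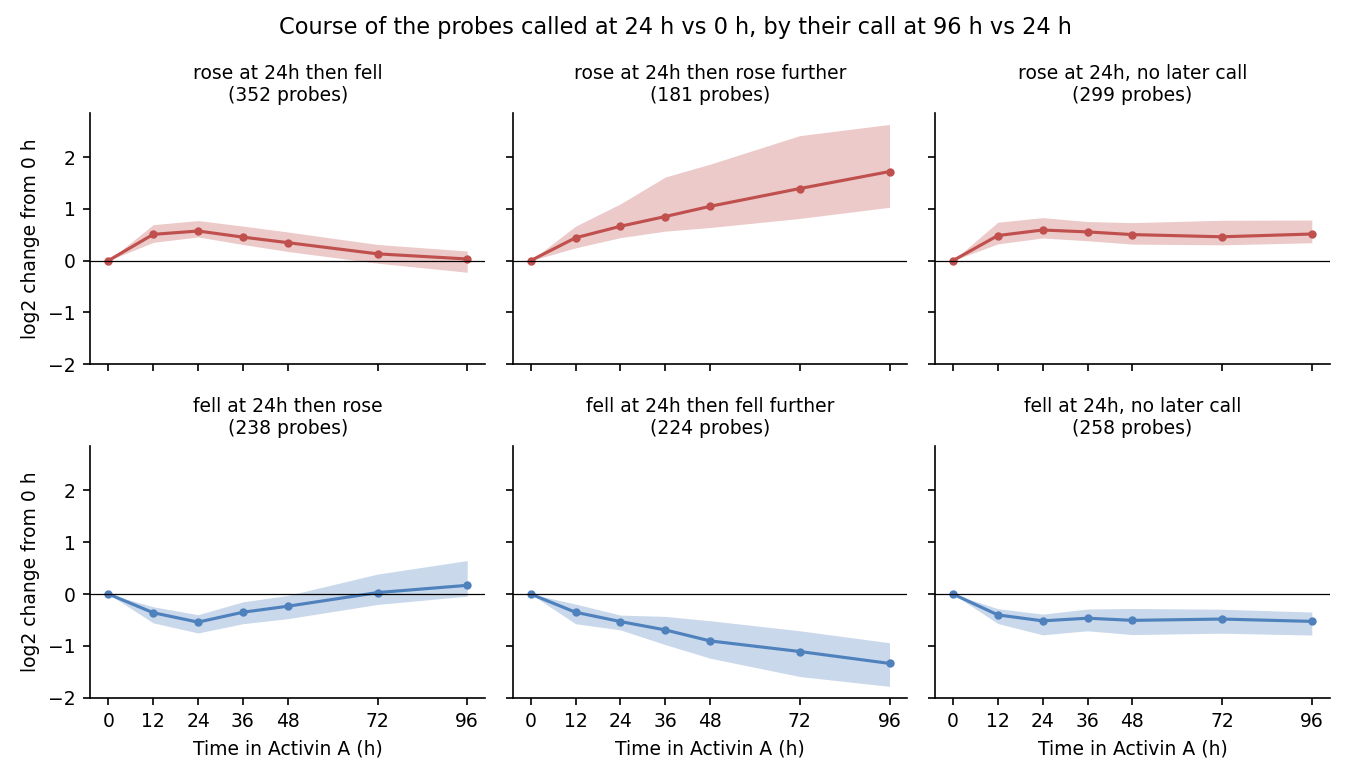
Median log2 change from 0 h (line) with its quartiles (band) against hours in Activin A, for the probes called at 24 h, split by their call between 24 h and 96 h. The 352 probes that rose and then fell return from a median of 0.57 at 24 h to 0.03 at 96 h, while the 181 that rose further reach 1.72.

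Detection itself changed over the course. By 96 h, 714 probes below detection on both 0 h arrays were detected on both arrays, 515 of them called as rises, and 81 of them were at least 4-fold higher with the level below detection at its bound. In the opposite direction 197 probes were lost from detection, 185 of them called as falls, and 13 were at least 4-fold lower. At 12 h the numbers were 229 gained and 98 lost. The 0 h arrays were the dimmest and detected the fewest probes, 10351 and 10275, against 11100 and 11012 on the 96 h arrays. Gains from 0 h are therefore not separated from a lower sensitivity of the 0 h arrays. The gain over the loss was not seen with a detection score of 1 as the limit, which gave 411 gained and 418 lost. With an array left out, detection was asked only of the remaining array of that time, which can only raise these numbers. Probes lost then numbered 371 and 378 without 0 h replicates 1 and 2, and 302 without 96 h replicate 1.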

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

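The test of a fault in the 24 h arrays alone, and the parting of these arrays for the probes that fell and then rose, were chosen after the results were seen, and the other tests before.

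The change from 0 h to 24 h and the change from 24 h to 96 h ran in opposite directions for 352 probes that rose and then fell, each step passing its own test. For chance high values on the shared 24 h arrays, the rise was taken from 1 of the 24 h arrays and the fall tested on the other. The overlap was then 1.29 and 1.61 times that of independent lists. This cannot decide the question, because both fits share the other arrays and so most of the estimate of each probe's spread. Probes with a low spread pass both tests more often, which alone raises the overlap above that of independent lists. As for scaling between arrays, the number was 388 with median scaling and 284 with cyclic loess, so a course of this kind was called under each. This cannot decide on scaling, because whether the same probes were called was not compared. Median scaling also changed the lists behind the number, from 832 to 1505 rises at 24 h and from 3092 to 1918 falls between 24 h and 96 h. With cyclic loess these were 797 and 2526. A fault of the 24 h arrays alone would leave these probes near their 0 h level at the other times, but their median log2 change from 0 h was 0.51 at 12 h (quartiles 0.35 to 0.69) and 0.454 at 36 h (0.31 to 0.67), against 0.57 at 24 h. With the probes chosen without the 0 h array they were measured against, the lower of these medians was 0.46. A biological course, in which part of the early response is transient, is a hypothesis that was not tested. Whether it would follow Activin A, the loss of FGF2 or time in culture was not tested either. A technical feature shared by the arrays of several early times was not tested and stays open. Chip positions are not known, and the median bead intensity per array also rose and then came partly back. It was 251 and 256 at 0 h, between 324 and 365 from 12 h to 48 h, and 293 and 323 at 96 h.

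The reverse course, a fall by 24 h and a rise by 96 h, was found for 238 probes, for 112 with median scaling and for 278 with cyclic loess. The number dropped with median scaling, so scaling between arrays stays open for this course too. With the 24 h arrays parted, the overlap was 1.51 and 1.63 times that of independent lists, which cannot decide on chance for the reason given above. The 238 also lay below 0 h at 12 h and 36 h, with medians of -0.36 and -0.35, against -0.54 at 24 h.

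A control feature with a bacterial gene name, lysA, which enters no comparison, had a detection score of 0.996263 on 96 h replicate 2, above the 0.99 limit, while its highest score at 0 h was 0.970. This was 1 of the 14 arrays, and the other 3 control features stayed below the limit on all 14.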

How the results depend on the processing

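The lists of genes (camera, fry and the estimated correlation), the choice of 1 probe per gene and the chip as a block were not run, because the files used here give neither gene names nor chips; testing all probes separately is what was done. The replicate block, the F test without 0 h and the other detection limits were chosen after seeing the data. Array weights, cyclic loess, an offset of 50 and detection on all 14 arrays moved none of the 15 counts of calls by over 1.5 times. The replicate numbers did not pair the samples (21 correlations of deviations, -0.13 to 0.17, 1 of them above 0.1), and a replicate block moved none of the 15 counts by that much, giving 1379 at 12 h, 5854 at 96 h and 62 from 12 h to 24 h. Without the 0 h arrays the F test called 5865. The 4 named probes had 36 calls over the 12 comparisons, and none changed direction in any alternative that gave a value. Of these calls, 25, all those at 24 h or later against 0 h among them, held in each alternative with a test, and 11 were lost in some. The 12 h calls of GI_40288196-S, GI_10835229-S and GI_38455405-S were lost in 17 of 24, 16 of 25 and 13 of 25, for the last 2 also when any 1 array of 0 h or 12 h was left out. In the authors' deposited table, GI_22538469-S changed by 6.01 at 24 h and 7.62 at 96 h on the log2 scale, by more than the replicate SD from 5.65 and 7.31. No background correction lowered them to 3.69 and 5.29, and GI_40288196-S to 1.19 and 4.76 from 3.27 and 7.54. Dim probes are limited by background: 12906 probes were not tested.

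A 2-fold minimum left 165, 234, 380, 672, 1121 and 1604 probes at 12, 24, 36, 48, 72 and 96 h against 0 h, then 28, 78, 82, 207 and 98 over the successive intervals and 1328 for 96 h against 24 h; 22 rose then fell and 15 fell then rose. A smaller set passes by construction. Fitting only the 4 arrays (2 residual degrees of freedom) gave 60, 218, 1319 and 1441 at 12 to 48 h, 0, 0 and 0 in the 3 intervals to 48 h (limma; 1355, 1819 and 2009 at an unadjusted p below 0.05), 87 and 196 in the later ones, and 60 and 20 for the probes that turned. No detection filter, which adds 12906 tests, gave 532, 582, 1229 and 2222 at 12 to 48 h, 29, 111, 74, 527 and 185 over the intervals, and 124 and 73 for the probes that turned. No background correction gave 305, 556, 816 and 1174 from 12 to 24, 24 to 36, 36 to 48 and 72 to 96 h, a variance trend 294, 530, 745 and 1133, and trend with robust estimation 299, 540, 783 and 1124; the cause was not tested. Median scaling gave 112 probes that fell then rose, and a detection score of 1 gave 411 gained and 418 lost by 96 h; the cause was not tested.

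Leaving out each array in turn gave 577 to 1503 at 12 h, 547 to 1522 at 24 h, 960 to 2389 at 36 h, 2252 to 3274 at 48 h, 3313 to 4780 at 72 h and 4675 to 5997 at 96 h. The intervals gave 20 to 91, 66 to 277, 59 to 334, 333 to 1151 and 125 to 624, 96 h against 24 h 4112 to 5624, and the F test 5609 to 6857. Probes that rose then fell numbered 126 to 351, those that fell then rose 92 to 240, those gained 911 to 990 and those lost 266 to 378. Counts cut the most came without an array of a time compared: 12 h replicate 2 (577 and 20), 24 h replicate 1 (547, 126 and 92), 36 h replicate 1 (960 and 66), 36 h replicate 2 (59), 72 h replicate 1 (333) and 96 h replicate 1 (125).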

Other observations

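The tests of a constant step and of the background below were chosen after the results were seen, and the others before.

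The identifiers of the probes end in S, A or I, which the files do not explain, and the classes differed in detection. Probes ending in A were tested most often, 1329 of 2182 (60.9%), against 9383 of 19254 (48.7%) for S and 732 of 2914 (25.1%) for I. Among those tested, 62.4% of A, 59.7% of S and 56.1% of I probes changed over the time course, and the differences were not tested. Tested I probes were also dimmer, with a median log2 level of 7.76 against 8.86 for S and 8.96 for A.

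Probes came into detection throughout the course. Of the probes detected at 96 h and below detection at 0 h, 133 were first detected on both arrays at 12 h, 75 at 24 h, 87 at 36 h, 67 at 48 h, 131 at 72 h and 221 at 96 h.

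The probe GI_41406065-A, chosen after its values were seen, was at 4.85 on 24 h replicate 1 and 11.50 on 24 h replicate 2, while the other 12 arrays lay between 11.24 and 12.48. Its detection score on the low array was 0.137 against 1 on the other, and the probe was not called at 24 h (adjusted p = 0.178).

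More probes changed in the first 12 h than in any later 12 h interval, 1576 against at most 304, and the order held in all 27 settings that gave both counts, with a lowest ratio of 2.01 for fitted changes of at least 2-fold (165 against 82). Bounded 2-fold changes followed it too, 85 against at most 57, while 2-fold changes without background correction were close, 16 rises and 2 falls against 17 rises. Bounded rises of at least 4-fold did not follow it, 6 against 12 from 24 h to 36 h. A constant technical step on the 0 h arrays would leave the 1576 probes in place between 24 h and 96 h. Their median change over that span, signed by the 12 h direction, was -0.0514 to -0.158 over the 4 pairings of single arrays. For the 165 with a fitted change of at least 2-fold it was -0.0481 to -0.25. This cannot decide, because it is not beyond the spread of the pairings and some probes could return with such a step also present. The lower brightness of the 0 h arrays would shift these probes between bright and dim replicates, and the shift seen was 0.207 of that expected at the median of 3 pairs, with a highest ratio of 0.329 and a lowest of -0.22, too wide to decide. These technical explanations, the change of growth factors after 0 h and time in culture cannot be told apart, because every 0 h array is a control array.

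At 96 h, rises of at least 4-fold outnumbered falls, 273 to 94 by fitted values and 197 to 71 when bounded. Among probes detected on all arrays of both times, 65.4% of such changes were rises, with an exact 95% interval above 50% that treats probes as independent. This cannot decide on falls cut short by the background. A probe dim at 0 h stays in that set after a 4-fold rise but leaves it after a 4-fold fall. By fitted values the ratio of rises to falls was 2.90, 3.44 with cyclic loess and 7.73 with median scaling. Rises were 73.1% and 89.7% with these 2 scalings among probes detected at both times. They cannot decide on scaling, because both moved the median of all tested probes up, from -0.04 to 0.03 and 0.24. A scaling that moves it down was not tried. Over 26 settings the ratio lay between 1.69 and 10.8, but not all of them test it. A variance trend, array weights, a replicate block and a fit of only the 4 arrays gave the same 273 and 94. These leave the fitted changes as they were. The change of growth factors and time in culture stay open, and no biological explanation was tested.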
